A study of Rattus norvegicus with 65 samples.

How the data were processed

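Liver RNA of 65 rats was measured on Affymetrix rat arrays, 1 per rat. The deposited values are log2 signals of 31099 probe sets, made by the authors with RMA, per the series' design text, which gives no version of RMA and says that 1 failed array was left out. RMA corrects background, normalizes by quantiles and summarises the probes of a probe set. The lowest values of the arrays (3.3312 to 3.412 in the genotoxic, 3.2294 to 3.3046 in the nongenotoxic and 2.2774 to 2.3995 in the test set) and the highest (15.7895 to 15.9207, 15.4231 to 15.5558 and 14.1916 to 14.7213) did not overlap between sets, so each set appears to have been normalized apart. Comparisons across sets (treated arrays with no controls, control with control, all 6 or both controls, placement as deposited) carry that difference too.

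Groups were taken from the titles, per the labels: 20 arrays in the genotoxic set with its control, 21 in the nongenotoxic set with its control and 24 in the test set. Short and long are labelled 3 and 72 h, whereas the treatment protocol says that repeated groups were dosed 3 times and autopsied 24 h after, so only the words short and long are used. Doses were used in no test, since some have no unit. Arrays have no read depth, and their number limits the precision.

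Of the probe sets, 20832 have exactly 1 gene symbol in the reference annotation, 436 have several and 9831 none, and 57 control probe sets were left out. For each of 14217 genes the probe set with the highest mean was used, and no older symbol needed updating. A gene was tested if it lay above the median of the table (log2 6.03, or 5.65 inside the test set) in at least 2 arrays. Linear models were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with 1 mean per group and plain eBayes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. The genotoxic and nongenotoxic sets were fitted together (41 arrays, 27 residual degrees of freedom, prior 4.02, 11007 genes), the test set with the 6 controls (30, 20, 3.16, 10507), and the test set alone (24, 16, 2.95, 10213). Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

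Before the data were examined, these comparisons were fixed: the class difference (mean effect of 3 genotoxic minus that of 3 nongenotoxic compounds, each against its own control), each compound against its control, the test compounds against both controls, durations, the controls, shared genes and held-out placement. Placement scores the mean of 50 up minus 50 down genes chosen without the compound. Genes are named by a fixed rule. In the class comparisons they are the 10 highest and 10 lowest called genes for which the genotoxic effects all lie on 1 side of the nongenotoxic ones. Elsewhere they are the 4 highest and 4 lowest called genes, with no overlap between the arrays of 2 compared groups (10% of genes by chance for 3 against 3). Chosen after the data were seen were the comparisons inside the test set, the duration test, pairs of compounds, long minus short of 1 compound, the clock gene score (mean of Bmal1, Npas2, Clock and Cry1 minus mean of Dbp, Nr1d1, Nr1d2, Per3 and Tef, centred within a set), placement relative to the mean of the test set and the simulated placement. So were the list members given as examples and the 66 list results printed.

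The 27 gene lists, written down before the values, were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 720 list tests 272 passed, and 22 passed with an estimated correlation too. The members counted are those that passed the filter in these livers, cell type markers included, and no cell shares were inferred from them.

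Alternatives were no filter, a stricter filter (log2 7.99), the mean of all probe sets, trend and robust, quantile normalization of all columns, 1 fit of all arrays, only the compared groups, a replicate block, each rat left out, all 6 controls, no controls, compound as a random block or as the replicate, 1 control set or a pooled control for the test set, and 20 or 200 genes for placement. The fit was tested on simulated data with 200 of 11007 genes changed (10213 inside the test set). Changes of log2 1 and 2 were recovered in 92% and 100% for class long, 96% and 100% for MeDAB long and 94% and 100% for DCP long inside the test set, with 9, 9 and 8 false calls.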

Results

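Liver expression was measured in 65 male Sprague-Dawley rats, 1 array per rat. The design text lists 10 hepatocarcinogens, among them diethylnitrosamine, methyleugenol and sodium nitrite, without pairing them with the titles' abbreviations, so the titles' names are used, with 2-AAF, 3MeDAB, 1,4-Dioxane and DL-Ethionine shortened. The titles put AAF, MeDAB and DEN in the genotoxic set, Dioxane, Clofibrate and Ethionine in the nongenotoxic set, and DCP, ME, SN and Urethane in a test set. Each compound has a short and a long group with 3 rats each except DEN short with 2. Each of the first 2 sets has 1 control group of 3 rats with no time given, and the test set has none. A rat is named by its group and replicate number, and rats that follow "without" were left out 1 at a time. Values are log2 signals, and differences are log2 differences ± SE from limma with Benjamini-Hochberg adjusted p-values. For a list the first adjusted p uses a preset correlation, and a list given no other passed with an estimated correlation too.

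**Figure D1:**
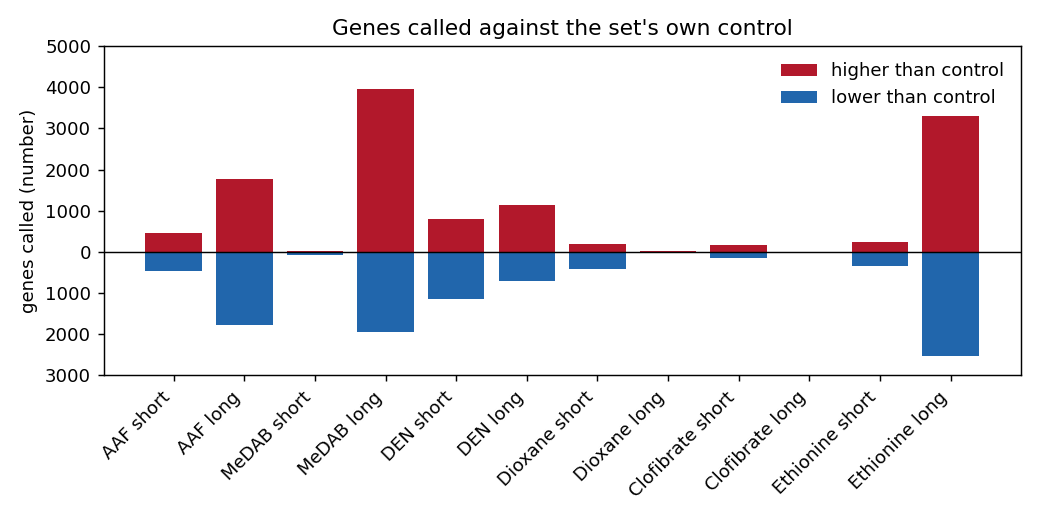
Number of genes called higher and lower than the control of the same set (bars above and below 0) in the 12 treated groups of the genotoxic and nongenotoxic sets. The bars run from 15 called genes in Clofibrate long to 5898 in MeDAB long.

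The class comparison at the short duration asked in which genes genotoxic and nongenotoxic compounds moved the liver apart. Cdkn1a, whose p53-induced product stops the cell cycle, was higher with the genotoxic compounds by 3.36 ± 0.50 (adjusted p = 0.000242). Its level was 10.8 ± 0.469 in AAF short, 9.39 ± 0.569 in MeDAB short and 11.7 ± 0.266 in DEN short against 7.63 ± 1.1 in their control (SD). Slc6a6 (2.74 ± 0.51), Zfp37 (2.13 ± 0.44), Mybl1 (2.07 ± 0.33), Tubb2a (2.05 ± 0.39) and Trim36 (2.00 ± 0.51) were also higher. Stac3 (3.11 ± 0.83), Obp3 (2.97 ± 0.65), Rprm (2.38 ± 0.69) and LOC102549203 (1.94 ± 0.46) were higher mainly by falls in the nongenotoxic groups. Stac3 was at -3.63 to -3.16 there and at -0.868 to 0.0755 in the genotoxic groups. The serine synthesis genes Phgdh (-3.29 ± 0.83) and Psat1 (-2.46 ± 0.73) were lower. So were Asns (-2.97 ± 0.74), Adh4 (-1.81 ± 0.34), Upk1b (-1.92 ± 0.46) and Efemp1 (-1.84 ± 0.54). Cd36 (-1.90 ± 0.38), Sult2a6 (-2.59 ± 0.47) and Edil3 (-2.01 ± 0.39) were lower mainly by rises in the nongenotoxic groups. Ugt2b, a glucuronosyltransferase gene, was at -5.57 ± 1.07, a difference that rests on its low level in the nongenotoxic control (6.59 ± 0.424) and was -0.56 between the treated arrays alone, across sets (adjusted p = 0.435). In all, 590 of 11007 genes passed, 259 higher and 331 lower (205 to 720 with 1 rat left out). Of 23 p53 targets, 6 were higher and 17 did not pass (9 were higher adjusted over the list alone, adjusted p = 4.41e-06), with Ccng1 at 0.93 ± 0.17, Aen at 1.11 ± 0.21 and Phlda3 at 0.88 ± 0.18. Of 44 PPAR alpha targets, 6 were lower and 38 did not pass (7 were lower adjusted over the list alone, adjusted p = 0.00197, 0.66 with an estimated correlation), with Cd36 at -1.90 ± 0.38 and Hadhb at -0.56 ± 0.13. Of 16 macrophage markers, 4 were lower and 12 did not pass (8 were lower adjusted over the list alone, adjusted p = 1.95e-06, 0.66 with an estimated correlation), with C1qb at -0.81 ± 0.16. With no controls the macrophage list did not pass (adjusted p = 0.609). Rats of a compound are not independent. With compound as a random block 5 genes passed, none named here. Compound means as replicates gave 693, but share their control's error, and Mybl1, Trim36, Ccng1, Aen and Phlda3 did not pass (adjusted p up to 0.501). Of 10 splits of the 6 compounds, 4 gave at least the real count, mixed ones with less control error. With a clock gene score (4 clock genes minus 5 output genes) as a covariate 182 genes passed, and Stac3 (2.71), Rprm (0.865), Phgdh (-2.39), Asns (-2.19), Psat1 (-1.79), Efemp1 (-1.89) and Hadhb (-0.485) did not (adjusted p up to 0.227, differences with the score in brackets). Rprm, Stac3, Phgdh, Asns, Trim36 and Upk1b did not pass without some rats, and Psat1 and Efemp1 without most (adjusted p up to 0.233).

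The same contrast at the long duration asked what stood after repeated dosing. Fabp2, a fatty acid binding protein gene, was higher with the genotoxic compounds by 2.70 ± 0.38 (adjusted p = 1.39e-05), and the adhesion gene Jam3 by 2.16 ± 0.25. The noncoding gene Pvt1 (1.98 ± 0.16), the carboxylesterase gene Ces2c (2.15 ± 0.29) and the small heat shock protein gene Hspb1 (1.83 ± 0.36) were higher too, with Snx10 (2.21 ± 0.58), Rgs5 (2.14 ± 0.36), Poteml2 (1.93 ± 0.48) and Hapln3 (1.78 ± 0.21). Raph1 was higher by 2.04 ± 0.39, with 1 of its 4 probe sets called. Rtp4 (-1.86 ± 0.37), Ifgga2l1 (-2.30 ± 0.44) and Mx2 (-1.96 ± 0.37) were lower, the last called in 1 of 2 probe sets. Oat (-2.17 ± 0.37), Got1 (-1.78 ± 0.52) and Bhmt (-1.82 ± 0.32) were lower as well, with Sult1c2 (-2.37 ± 0.45), Ccdc141 (-1.92 ± 0.53) and Rnf125 (-1.69 ± 0.43). Ugt2b was at -5.21 ± 1.06, and at -0.19 between the treated arrays alone, across sets (adjusted p = 0.774). In all, 1294 genes passed, 859 higher and 435 lower (778 to 1812 with 1 rat left out). Of 23 p53 targets, 9 were higher and 14 did not pass (10 were higher adjusted over the list alone, adjusted p = 5.83e-06), with Mgmt at 1.78 ± 0.15, Ccng1 at 1.59 ± 0.17 and Mdm2 at 1.44 ± 0.23. Ethionine long raised this list too. Of 23 interferon response genes, 13 were lower and 10 did not pass (17 were lower adjusted over the list alone, adjusted p = 2.5e-12, 0.0875 with an estimated correlation), with Mx1 at -1.89 ± 0.39, Oasl at -1.54 ± 0.19 and Isg15 at -1.45 ± 0.26. Of the 3 nongenotoxic compounds averaged, Ethionine weighed most, with Isg15 at 4.20 ± 0.22 against its control, 0.37 ± 0.22 in Dioxane long and 0.56 ± 0.22 in Clofibrate long, and no list member was shared lower by the 3 genotoxic compounds. Of 24 urea cycle and amino acid breakdown genes, 1 was higher, 7 were lower and 16 did not pass (1 was higher and 9 were lower adjusted over the list alone, adjusted p = 4.67e-06, 0.144 with an estimated correlation), with Gls2 at -1.62 ± 0.17. Of 29 NRF2 targets, 5 were higher and 24 did not pass (8 were higher adjusted over the list alone, adjusted p = 0.00119, 0.424 with an estimated correlation), with Srxn1 at 1.47 ± 0.38. Of 20 methionine and polyamine genes, 1 was higher, 7 were lower and 12 did not pass (3 were higher and 8 were lower adjusted over the list alone, adjusted p = 0.0128, 0.194 with an estimated correlation), with Mat1a at -0.79 ± 0.13. The last list did not pass with no controls (adjusted p = 0.0983). With compound as a random block 0 genes passed by limma, and with compound means as replicates 2 did, so these calls speak of rats given these 6 compounds. All 10 splits gave at least the real count, mixed ones with less control error. Ccdc141 and Got1 did not pass without some rats, and Rnf125 without genotoxic control 2 (adjusted p up to 0.102).

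**Figure D2:**
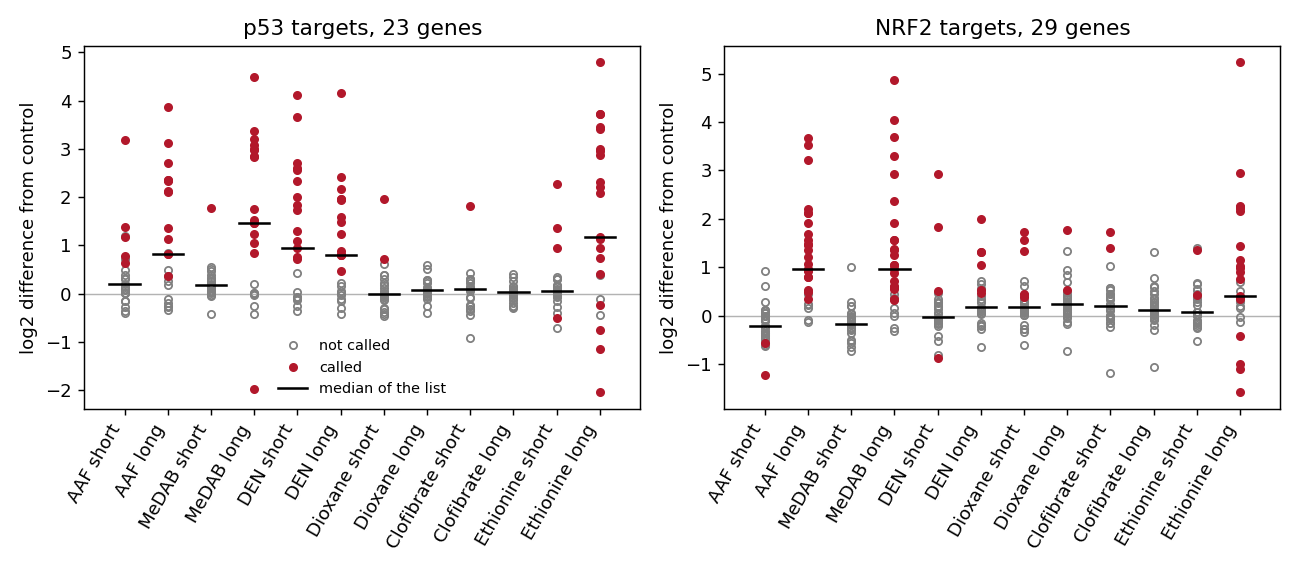
Log2 difference from the own set control (vertical axis) of the 23 p53 targets and the 29 NRF2 targets in each of the 12 treated groups, with called genes in red, others in grey and a line at the median. Called p53 targets number 14 in DEN short and 1 in MeDAB short.

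AAF against the genotoxic control showed what this compound did at each duration. Cyp1a1, the enzyme gene that the aryl hydrocarbon receptor switches on, rose by 6.07 ± 0.60 in the short group (adjusted p = 2.51e-07), from 5.62 ± 0.206 to 11.7 ± 1.61 (SD, n = 3 each). Cdkn1a rose by 3.19 ± 0.43, the clock-linked deadenylase gene Noct by 3.17 ± 0.76 and the zinc finger gene Zfp354a by 2.89 ± 0.66. The lipogenic gene Mid1ip1 fell (-2.48 ± 0.45), with Rtp3 (-1.96 ± 0.37), Ifgga2l1 (-1.81 ± 0.38) and Slc25a30 (-1.77 ± 0.32). In total 470 genes rose and 465 fell (399 to 1356 with 1 rat left out). Out of 23 p53 targets, 5 rose and 18 did not pass (7 rose adjusted over the list alone, adjusted p = 0.00172), with Tp53inp1 at 1.18 ± 0.23. Of 18 gluconeogenesis and glucocorticoid genes, 9 rose and 9 did not pass (12 rose adjusted over the list alone, adjusted p = 2.94e-09), with Ppargc1a at 2.23 ± 0.32 and Fkbp5 at 1.93 ± 0.36. Noct did not pass without some rats (adjusted p up to 0.105).

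In AAF long, Cyp1a1 stood 6.50 ± 0.60 above the control, Mybl1, a MYB family transcription factor gene, 4.44 ± 0.28, Cdkn1a 3.87 ± 0.43 and Snx10 3.80 ± 0.50. The fatty acid desaturase gene Scd fell (-5.47 ± 0.53), as did Stac3 (-5.43 ± 0.71), the liver transcription factor gene Onecut1 (-4.35 ± 0.76) and Fam111a (-6.07 ± 1.53). Fam111a lay over 3 log2 apart between rats of 1 group in 13 of the 22 groups, so its calls in any comparison are uncertain. In total 1764 genes rose and 1774 fell. Of 23 p53 targets, 13 rose and 10 did not pass (15 rose adjusted over the list alone, adjusted p = 8.19e-10), with Mgmt at 3.12 ± 0.13 and Mdm2 at 2.71 ± 0.20. Among 29 NRF2 targets, 22 rose and 7 did not pass (25 rose adjusted over the list alone, adjusted p = 3.7e-13, 0.0863 with an estimated correlation), with Gpx2 at 3.68 ± 0.76 and Nqo1 at 1.49 ± 0.24. Of 7 AHR targets, 4 rose and 3 did not pass (4 rose adjusted over the list alone, adjusted p = 0.00969, 0.318 with an estimated correlation). Of 16 CAR and PXR targets, 9 rose, 1 fell and 6 did not pass (10 rose and 1 fell adjusted over the list alone, adjusted p = 0.00046, 0.0863 with an estimated correlation), with Ces2c at 3.27 ± 0.25 and Ugt2b1 at 1.50 ± 0.20. Of 40 proliferation genes, 1 rose, 25 fell and 14 did not pass (1 rose and 27 fell adjusted over the list alone, adjusted p = 5.43e-09, 0.318 with an estimated correlation), with Ccnb2 at -2.45 ± 0.32 and Mki67 at -1.85 ± 0.34. Of 26 acute phase and inflammation genes, 11 fell and 15 did not pass (11 fell adjusted over the list alone, adjusted p = 0.000835, 0.318 with an estimated correlation), with A2m at -3.52 ± 0.67. Of 14 heat shock genes, 6 rose, 1 fell and 7 did not pass (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.00634, 0.334 with an estimated correlation), with Hspb1 at 1.64 ± 0.31. Of 15 leukocyte markers, 5 fell and 10 did not pass (6 fell adjusted over the list alone, adjusted p = 0.0174, 0.334 with an estimated correlation), with Ptprc at -0.83 ± 0.19. Without AAF long 3, the heat shock list (adjusted p = 0.107) and the leukocyte list (adjusted p = 0.142) did not pass.

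MeDAB raised Cyp1a1 in the short group by 5.62 ± 0.60 (adjusted p = 1.55e-06), to 11.2 ± 0.47 (SD, n = 3). The transcription factor gene Sall1 rose by 1.88 ± 0.29, Cdkn1a by 1.77 ± 0.43 and the folate carrier gene Slc25a32 by 1.30 ± 0.30. Chac1, a gene of glutathione breakdown, fell (-1.83 ± 0.44), with Ifgga2l1 (-1.65 ± 0.38), Slc25a30 (-1.47 ± 0.32) and Id3 (-1.44 ± 0.23). In total 27 genes rose and 74 fell (12 to 175 with 1 rat left out), or 54 and 65 after quantile normalization of the 65 columns. Among 23 p53 targets, 1 rose and 22 did not pass (1 rose adjusted over the list alone, adjusted p = 0.000328). With only the arrays of the compared groups 5 genes passed, and Sall1, Cdkn1a, Ifgga2l1, Slc25a30 and Id3 did not (adjusted p up to 0.317). Ifgga2l1 did not pass without some rats, and Slc25a32, Slc25a30, Cdkn1a and Chac1 without most (adjusted p up to 0.233). Without genotoxic control 1 Cdkn1a was at 1.14.

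MeDAB long changed far more genes, 3955 up and 1943 down. Cyp1a1 rose by 6.59 ± 0.60, Mybl1 by 6.56 ± 0.28, the metalloprotease gene Adam8 by 5.69 ± 0.21 (adjusted p = 1.06e-19) and the aldo-keto reductase gene Akr1b7 by 5.49 ± 0.68. The steroid reductase gene Akr1c1 fell (-5.78 ± 0.76), and so did Dhrs7l1 (-7.20 ± 0.71), Obp3 (-6.21 ± 0.55) and Scd (-5.71 ± 0.53). Out of 23 p53 targets, 15 rose, 1 fell and 7 did not pass (15 rose and 2 fell adjusted over the list alone, adjusted p = 7.41e-05), with Mdm2 at 3.21 ± 0.20 and Gdf15 at 3.37 ± 0.41. Out of 29 NRF2 targets, 22 rose and 7 did not pass (22 rose adjusted over the list alone, adjusted p = 0.000151, 0.372 with an estimated correlation), with Gpx2 at 4.05 ± 0.76. Of 20 male growth hormone genes, 1 rose and 19 fell (1 rose and 19 fell adjusted over the list alone, adjusted p = 6.94e-17), with Cyp2c11 at -5.26 ± 0.13. Of 17 bile acid synthesis and transport genes, 15 fell and 2 did not pass (15 fell adjusted over the list alone, adjusted p = 1.14e-09, 0.0515 with an estimated correlation), with Slc10a1 at -3.62 ± 0.33. Of 18 lipogenesis genes, 1 rose, 13 fell and 4 did not pass (1 rose and 13 fell adjusted over the list alone, adjusted p = 6.33e-08, 0.108 with an estimated correlation), with Thrsp at -4.64 ± 0.53. Of 19 hepatocyte markers, 1 rose, 12 fell and 6 did not pass (1 rose and 12 fell adjusted over the list alone, adjusted p = 3.45e-06, 0.104 with an estimated correlation), with Apoa2 at -2.52 ± 0.16. Of 3 pancreas markers, 2 fell and 1 did not pass (2 fell adjusted over the list alone, adjusted p = 0.0229, 0.162 with an estimated correlation), with Cela1 at -2.16 ± 0.20. The Gapdh 3' minus 5' probe difference, a sign of RNA quality, was 0.339 ± 0.0858 against 0.51 ± 0.107 in the control (SD), with no overlap of rats.

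DEN raised the stress transcription factor gene Atf3 in the short group by 5.34 ± 0.50, Mybl1 by 4.90 ± 0.32 (adjusted p = 1.25e-12), Cdkn1a by 4.11 ± 0.48 and the cytokine receptor gene Tnfrsf12a by 3.66 ± 0.34, in 2 rats against 3. The orphan nuclear receptor gene Esrrg fell (-2.20 ± 0.44), with Fam111a (-4.80 ± 1.71), Nim1k (-2.06 ± 0.62) and LOC102554026 (-1.99 ± 0.42). In total 793 genes rose and 1139 fell (857 to 1513 with 1 rat left out). Of 23 p53 targets, 14 rose and 9 did not pass (15 rose adjusted over the list alone, adjusted p = 1.85e-12), with Ccng1 at 2.70 ± 0.17 and Gdf15 at 3.66 ± 0.46. The Gapdh 3' minus 5' difference was 0.747 ± 0.00438 (SD), with no overlap with the control either. Fam111a did not pass with any 1 rat left out, and Nim1k without most (adjusted p up to 0.226).

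In DEN long, Adam8 rose by 5.77 ± 0.21 (adjusted p = 3.02e-19), Mybl1 by 4.92 ± 0.28, Cdkn1a by 4.15 ± 0.43 and Vxn by 3.66 ± 0.24. Onecut1 fell (-3.66 ± 0.76), as did Stac3 (-3.41 ± 0.71), the mitochondrial carrier gene Slc25a30 (-2.87 ± 0.32) and the dicarboxylate transporter gene Slc13a3 (-2.76 ± 0.25). In total 1143 genes rose and 695 fell. Among 23 p53 targets, 14 rose and 9 did not pass (14 rose and 1 fell adjusted over the list alone, adjusted p = 2.48e-10), with Ccng1 at 2.42 ± 0.15 and Mgmt at 2.17 ± 0.13. Among 40 proliferation genes, 28 rose and 12 did not pass (33 rose adjusted over the list alone, adjusted p = 7.9e-16, 0.21 with an estimated correlation), with Mcm6 at 1.77 ± 0.20 and Ccnd1 at 1.68 ± 0.28. Among 16 macrophage markers, 9 rose, 1 fell and 6 did not pass (9 rose and 1 fell adjusted over the list alone, adjusted p = 2.55e-05, 0.408 with an estimated correlation), with Gpnmb at 2.91 ± 0.33 and Cd14 at -2.03 ± 0.24. Of 19 stellate cell and fibroblast markers, 8 rose and 11 did not pass (9 rose adjusted over the list alone, adjusted p = 2.55e-05, 0.21 with an estimated correlation), with Dcn at 2.25 ± 0.43.

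Pairs of genotoxic compounds were set against each other with no control. DEN and AAF differed in 1344 genes at the short and 3419 at the long duration, DEN and MeDAB in 1599 and 5422, and AAF and MeDAB in 197 and 5405. Genes higher and lower in AAF than in MeDAB numbered 176 and 21 at the short and 1639 and 3766 at the long duration, or 147 and 45, and 2016 and 2502, after quantile normalization. Those higher and lower in DEN than in MeDAB long went from 1822 and 3600 to 2250 and 2768. The median difference of all genes between AAF and MeDAB long was -0.149, and -0.038 after that normalization. The AAF and MeDAB short count ran from 21 (without AAF short 1) to 497 with single rats left out.

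Dioxane, a solvent, was set against the nongenotoxic control. In the short group Ugt2b stood 6.76 ± 0.92 above it, the clock output gene Usp2 3.02 ± 0.65, the immediate early gene Egr1 2.79 ± 0.61 and Cyp1a1 2.75 ± 0.60. The lipocalin gene Obp3 fell (-4.00 ± 0.55, adjusted p = 7.29e-05), with Onecut1 (-3.36 ± 0.76), Stac3 (-3.16 ± 0.71) and the growth hormone feedback gene Socs2 (-2.77 ± 0.57). Ugt2b was low in all 3 nongenotoxic control rats and in 8 rats of other groups, so its differences from that control are uncertain. In total 200 genes rose and 405 fell (203 to 586 with 1 rat left out). Among 18 gluconeogenesis and glucocorticoid genes, 5 rose and 13 did not pass (8 rose and 1 fell adjusted over the list alone, adjusted p = 1.61e-05, 0.211 with an estimated correlation), with Fkbp5 at 2.03 ± 0.36 and Igfbp1 at 1.50 ± 0.32. The actin 3' minus 5' probe difference was 2.38 ± 0.318 in Dioxane short, 2.82 ± 0.131 in Dioxane long and 2.8 ± 0.153 in Clofibrate long against 3.09 ± 0.119 in the control, and that of Gapdh 0.42 ± 0.0658 in Dioxane short against 0.68 ± 0.207 (SD), with no overlap of rats. Adding the clock gene score as a covariate gave 154 genes, and Usp2 (1.46), Onecut1 (-3.14), Stac3 (-2.69) and Socs2 (-1.77) did not pass (adjusted p up to 0.149). Onecut1 and Usp2 did not pass without some rats, and Egr1 and Stac3 without Dioxane short 1 (adjusted p up to 0.0811).

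In Dioxane long Ugt2b (6.80 ± 0.92) and Ugt2b1 (1.59 ± 0.20, adjusted p = 5.18e-05) rose, with the glutathione transferase gene Gsta3 (1.78 ± 0.34) and the replication gene Mcm6 (1.15 ± 0.20). Ugt2b1 deviated most closely with Ugt2b inside groups, so its differences from the nongenotoxic control are uncertain too. The ceramide synthase gene Cers6 fell (-0.92 ± 0.19), with Slc25a30 (-1.85 ± 0.32), Hhex (-1.44 ± 0.28) and Fam117b (-0.94 ± 0.14). In total 10 genes rose and 8 fell (3 to 70 with 1 rat left out). Of 29 NRF2 targets, 2 rose and 27 did not pass (7 rose adjusted over the list alone, adjusted p = 3.11e-07, 0.684 with an estimated correlation). Hhex did not pass without some rats; Gsta3 and Cers6 without most; and Mcm6 and Slc25a30 without Dioxane long 3 (adjusted p up to 0.278).

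Clofibrate is a fibrate drug that activates the fatty acid receptor PPAR alpha. In the short group Ugt2b stood 6.66 ± 0.92 above the control, Enc1 2.76 ± 0.36, Sult2a6 2.65 ± 0.41 (adjusted p = 0.000429) and the G protein regulator gene Rgs16 2.55 ± 0.38. Stac3, Obp3, Socs2 and Rprm fell (-3.63 ± 0.71, -2.99 ± 0.55, -2.82 ± 0.57 and -2.11 ± 0.59). In total 170 genes rose and 149 fell (46 to 393 with 1 rat left out). Among 44 PPAR alpha targets, 12 rose and 32 did not pass (26 rose adjusted over the list alone, adjusted p = 6.22e-17, 0.2 with an estimated correlation), with Cd36 at 1.70 ± 0.33 and Ehhadh at 1.66 ± 0.28. The clock gene score as a covariate brought the count to 43, and Stac3 (-3.17), Socs2 (-1.82), Rprm (-0.382) and Cd36 (1.3) did not pass (adjusted p up to 0.672). Socs2 did not pass without some rats; Rprm without most; and Stac3 without Clofibrate short 2 (adjusted p up to 0.269).

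In Clofibrate long Ugt2b (6.93 ± 0.92) and Ugt2b1 (1.55 ± 0.20, adjusted p = 8.86e-05) rose, with Rcan2 (1.04 ± 0.22) and Syne4 (0.81 ± 0.13). The peroxisomal lyase gene Hacl1 fell (-0.91 ± 0.16), with Ppp1r10 (-0.94 ± 0.19), Cers6 (-0.86 ± 0.19) and Rif1 (-0.68 ± 0.14). In total 7 genes rose and 8 fell (2 to 44 with 1 rat left out). Out of 44 PPAR alpha targets, none passed by limma (3 at unadjusted p under 0.05, 1 fell adjusted over the list alone, adjusted p = 0.047, 0.777 with an estimated correlation). With the clock gene score as a covariate the list did not pass (adjusted p = 0.13). With the mean of all probe sets Rif1 was at -0.265 and did not pass (adjusted p = 0.419). Hacl1 did not pass without some rats; Rcan2 with any 1 rat left out; Ppp1r10, Cers6 and Rif1 without most; and Syne4 without Clofibrate long 2 (adjusted p up to 0.396). The PPAR alpha list did not pass without Clofibrate long 1 (adjusted p = 0.0527), 2 (0.0973) or 3 (0.0674), nor without nongenotoxic control 2 (0.148) or 3 (0.12).

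Ethionine is an analogue of methionine. In the short group Ugt2b stood 6.83 ± 0.92 above the control, the histone genes H4cl1 3.62 ± 0.71 and H4f3 3.02 ± 0.66, and Noct 3.48 ± 0.76. The clock gene Npas2 fell (-2.29 ± 0.42, adjusted p = 0.00192), with Stac3 (-3.55 ± 0.71), Obp3 (-2.75 ± 0.55) and Socs2 (-2.74 ± 0.57). In total 231 genes rose and 336 fell (70 to 1179 with 1 rat left out). Of 17 circadian clock genes, 7 rose, 3 fell and 7 did not pass (12 rose and 3 fell adjusted over the list alone, adjusted p = 2e-04), with Wee1 at 1.47 ± 0.24. Among 16 CAR and PXR targets, 3 rose and 13 did not pass (9 rose adjusted over the list alone, adjusted p = 8.82e-05), with Ugt2b1 at 1.31 ± 0.20. The clock gene score as a covariate brought the count to 20, and H4cl1 (3.27), Noct (2.27), H4f3 (2.71), Stac3 (-2.99), Obp3 (-2.52), Socs2 (-1.52), Npas2 (-1.04) and Wee1 (1.17) did not pass (adjusted p up to 0.206), where Npas2 is a member of the score. With only the arrays of the compared groups 13 genes passed, and H4cl1, Noct, H4f3, Stac3, Obp3, Socs2 and Wee1 did not (adjusted p up to 0.239). Noct, H4f3 and Socs2 did not pass without some rats, and H4cl1 and Obp3 without Ethionine short 3 (adjusted p up to 0.107).

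In Ethionine long the thioesterase gene Acot1 rose by 5.80 ± 0.86, Ugt2b by 6.78 ± 0.92, Ugt2b7 by 5.25 ± 0.33 and the aldo-keto reductase gene Akr1b8 by 5.23 ± 0.50. The desaturase gene Fads1 fell (-5.11 ± 0.28), as did the amino acid oxidase gene Dao (-5.57 ± 0.24, adjusted p = 1.78e-18), Stac3 (-6.35 ± 0.71) and the glutathione transferase gene Gstp3 (-6.04 ± 0.44). In total 3306 genes rose and 2536 fell. Out of 23 p53 targets, 16 rose, 4 fell and 3 did not pass (16 rose and 5 fell adjusted over the list alone, adjusted p = 2.3e-05), with Cdkn1a at 4.79 ± 0.43 and Mdm2 at 3.72 ± 0.20. Dcxr was a p53 target that fell (-2.05 ± 0.17). Among 23 interferon response genes, 21 rose, 1 fell and 1 did not pass (21 rose and 1 fell adjusted over the list alone, adjusted p = 3.96e-07, 0.198 with an estimated correlation), with Isg15 at 4.20 ± 0.22 and Oasl at 4.23 ± 0.16. Of 20 cholesterol synthesis genes, 1 rose, 18 fell and 1 did not pass (1 rose and 18 fell adjusted over the list alone, adjusted p = 5.61e-09, 0.198 with an estimated correlation), with Cyp51 at -2.76 ± 0.27. Of 21 unfolded protein response genes, 1 rose, 18 fell and 2 did not pass (1 rose and 18 fell adjusted over the list alone, adjusted p = 1.23e-07, 0.198 with an estimated correlation), with Calr at -1.28 ± 0.10. Of 15 endothelial markers, 12 rose and 3 did not pass (12 rose and 1 fell adjusted over the list alone, adjusted p = 0.00549, 0.549 with an estimated correlation), with Lyve1 at 1.51 ± 0.23.

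Ethionine differed from Dioxane in 94 genes at the short and 6115 at the long duration, and from Clofibrate in 113 and 6113. Dioxane and Clofibrate differed in 0 genes by limma at either duration, with 1128 genes at the short and 210 at the long duration under an unadjusted p of 0.05. The short count ran from 0 (without Dioxane short 1) to 51 with single rats left out.

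Long minus short groups, averaged over the compounds of a set, used no controls. In the genotoxic set 4014 genes rose and 2318 fell, with 3938 called in AAF, 6522 in MeDAB and 3330 in DEN taken singly. Adam8 rose by 4.88 ± 0.13 (adjusted p = 5.1e-24), with Mybl1 (2.88 ± 0.17), Fabp2 (2.86 ± 0.20) and Vxn (2.78 ± 0.14), and the serine dehydratase gene Sds fell (-4.77 ± 0.38), with Stac3 (-4.45 ± 0.42), Scd (-4.44 ± 0.32) and Dhrs7l1 (-3.31 ± 0.42). Among 29 NRF2 targets, 26 rose, 1 fell and 2 did not pass (26 rose and 1 fell adjusted over the list alone, adjusted p = 2.7e-07, 0.148 with an estimated correlation), with Akr1b8 at 2.70 ± 0.30. Among 20 male growth hormone genes, 1 rose and 19 fell (1 rose and 19 fell adjusted over the list alone, adjusted p = 2.9e-12), with Cyp2c11 at -2.37 ± 0.081. Among 24 urea cycle and amino acid breakdown genes, 18 fell and 6 did not pass (20 fell adjusted over the list alone, adjusted p = 7.71e-10), with Oat at -2.90 ± 0.19. In the nongenotoxic set 2402 genes rose and 1560 fell, with 5684 called in Ethionine, 584 in Dioxane and 382 in Clofibrate taken singly. The cell cycle gene Rprm rose by 3.14 ± 0.34, the clock gene Bmal1 by 2.85 ± 0.30, Slc6a6 by 2.45 ± 0.25 and the tubulin gene Tubb2a by 2.35 ± 0.19. The clock output gene Dbp fell (-3.57 ± 0.46), as did Rgs16 (-2.68 ± 0.22), Usp2 (-2.58 ± 0.38) and Thrsp (-2.36 ± 0.30). Of 23 p53 targets, 15 rose, 4 fell and 4 did not pass (15 rose and 4 fell adjusted over the list alone, adjusted p = 7.24e-05), with Cdkn1a at 1.92 ± 0.25. This list passed in Ethionine (16 higher, adjusted p = 7.76e-05) and not in Dioxane (0.62) or Clofibrate (0.606), and Cdkn1a went from 7.61 ± 0.195 to 13.1 ± 0.154 in Ethionine, 8.94 ± 0.645 to 8.21 ± 0.238 in Dioxane and 7.42 ± 0.953 to 8.41 ± 0.128 in Clofibrate (SD). Among 20 cholesterol synthesis genes, 17 fell and 3 did not pass (17 fell adjusted over the list alone, adjusted p = 5.05e-13, 0.0975 with an estimated correlation), with Sqle at -1.74 ± 0.15. Of these 19 fell in Ethionine, 2 in Dioxane and 1 in Clofibrate. Among 17 circadian clock genes, 5 rose, 11 fell and 1 did not pass (5 rose and 11 fell adjusted over the list alone, adjusted p = 0.0141, 0.154 with an estimated correlation). Adding the clock gene score as a covariate, 1113 genes passed, Dbp turned to 0.73, and Rprm (0.124), Bmal1 (0.13), Slc6a6 (0.613), Usp2 (0.144), Cdkn1a (0.268) and the clock list did not (adjusted p up to 0.898). Dbp, Bmal1 and most of that list are members of the score, so their outcome is fixed by its construction, here and in the comparisons below. 

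Class by duration, tested as an interaction with rats and not compounds as replicates, passed in 4431 genes. Of these, 2708 had a higher and 1723 a lower genotoxic minus nongenotoxic difference at the long duration. They speak of rats given these compounds. Adam8 (3.88 ± 0.18, adjusted p = 1.78e-16), Snx10 (3.29 ± 0.42), Dbp (3.21 ± 0.66) and the glutathione peroxidase gene Gpx2 (3.19 ± 0.63) were higher, and Stac3 (-4.79 ± 0.59), Scd (-3.95 ± 0.44), Onecut1 (-3.79 ± 0.63) and Obp3 (-3.71 ± 0.46) lower. Out of 29 NRF2 targets, 21 were higher, 1 was lower and 7 did not pass (22 were higher and 1 was lower adjusted over the list alone, adjusted p = 1.14e-05, 0.324 with an estimated correlation), with Abcc3 at 2.61 ± 0.36. Out of 23 interferon response genes, 15 were lower and 8 did not pass (16 were lower adjusted over the list alone, adjusted p = 7.44e-07, 0.296 with an estimated correlation), with Isg15 at -1.42 ± 0.19. In Ethionine, Isg15 went from 8.25 ± 0.503 to 13 ± 0.325 (SD). With the clock gene score as a covariate 2140 genes passed, Dbp was at -0.0905 and Gpx2 (2.19) did not pass (adjusted p = 0.0616).

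**Figure D3:**
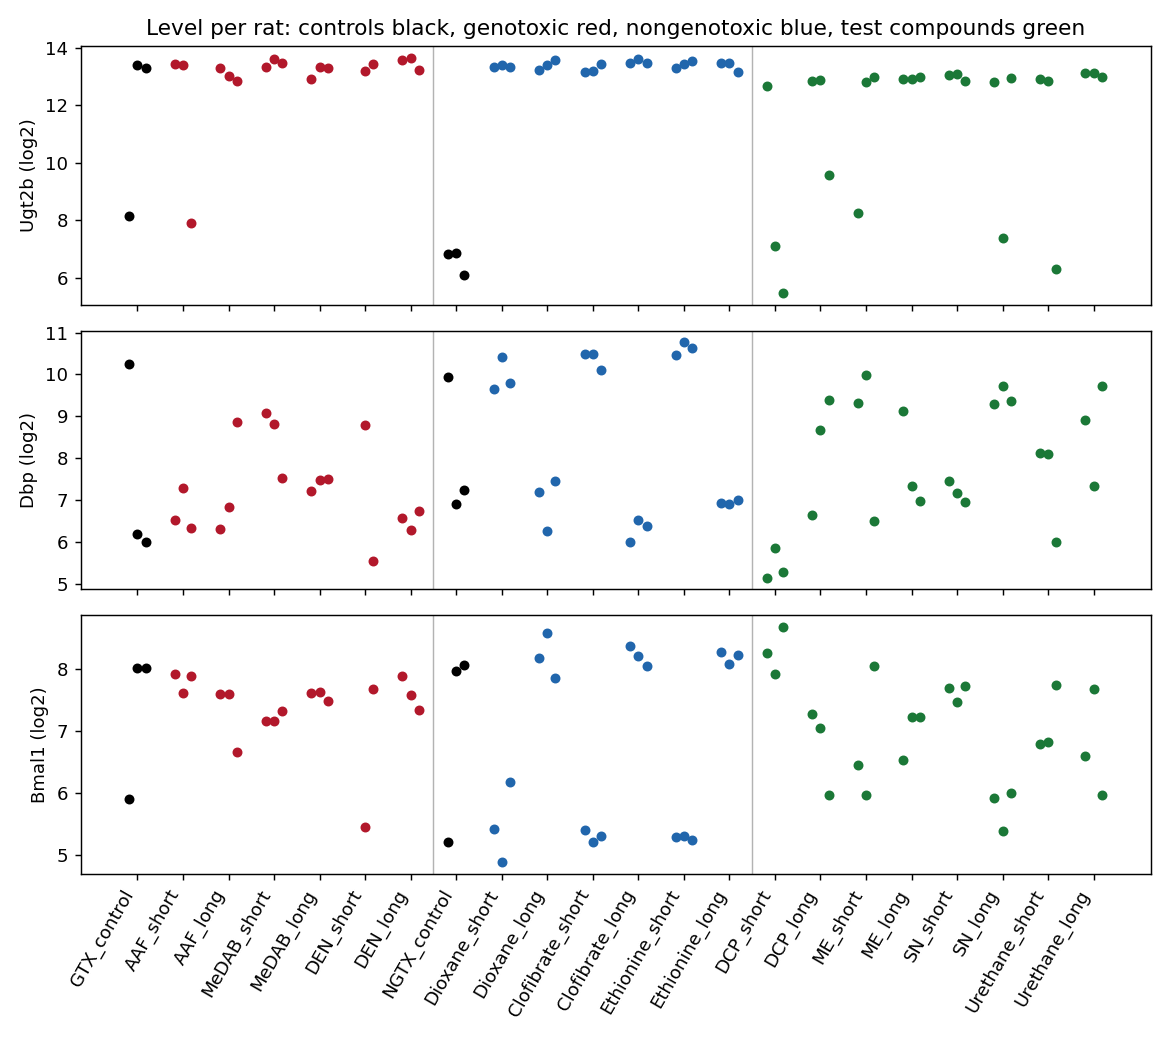
Log2 level (vertical axis) of Ugt2b, Dbp and Bmal1 in each rat of the 22 groups, with controls in black, genotoxic groups in red, nongenotoxic groups in blue and test groups in green. Ugt2b falls below 10 in 11 of the 65 rats, the 3 rats of the nongenotoxic control among them.

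Genes called the same way in all 3 compounds of a set against the set's control were counted to find marks common to a set. In the genotoxic set 634 genes were shared at the long duration, 296 up and 338 down, where independent lists give 65.8 and 19.8. Of the 23 p53 targets, 13 were shared, namely Aen, Bbc3, Ccng1, Cdkn1a, Fas, Gdf15, Mdm2, Mgmt, Perp, Phlda3, Plk2, Tp53inp1 and Zmat3. At the short duration 39 were shared, 10 up and 29 down (independent lists, 0.0831 and 0.323), Cdkn1a among those up and Id3 among those down. Quantile normalization made this 24 up and 23 down. The nongenotoxic set shared 88 genes at the short duration, 31 up and 57 down (independent lists, 0.0648 and 0.167), with Ugt2b, Sult2a6 and Gadd45a up and Stac3, Obp3, Socs2 and Npas2 down. At the long duration it shared 5 genes, chosen for naming after their values were seen: Ugt2b, Sult2a6, Ugt2b1 and Coq5 up and Cers6 down (independent lists, 0.00191 and 0.00134, and 4 up and 2 down after quantile normalization). Genes called in opposite directions numbered 12, 330, 0 and 5 in the same order (short and long genotoxic, short and long nongenotoxic). In 100 simulations of unchanged groups limma gave 0 shared genes, no baseline where many genes are called. Shared controls of 3 rats do not split in parts of at least 2, so they can give part of the excess. With the clock gene score as a covariate the short nongenotoxic set shared 5 genes. With 1 rat left out the short and long genotoxic counts ran from 5 to 49 and 420 to 730, the short nongenotoxic one from 21 to 157 (without nongenotoxic control 1) and the long one from 2 to 19.

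The test compounds were to be compared with both control groups, but the test set appears to have been normalized apart and has no control. That comparison called 8736 (582 up, 8154 down) and 8323 (493, 7830) genes for DCP short and long, 8271 (374 up, 7897 down) and 8306 (414, 7892) genes for ME short and long, 8097 (372 up, 7725 down) and 8312 (355, 7957) genes for SN short and long, 8534 (354 up, 8180 down) and 8402 (382, 8020) genes for Urethane short and long. No gene is named from it. The median difference of all genes lay between -0.568 and -0.452. Quantile normalization of the 65 columns brought it to between -0.0888 and -0.0148, and the short and long calls split into 2447 up and 3817 down and 2679 and 3047 for DCP, 2365 and 3077 and 2619 and 3012 for ME, 2492 and 2905 and 2630 and 2976 for SN, and 2456 and 2963 and 2841 and 3138 for Urethane. The genotoxic and nongenotoxic controls, which also appear to have been normalized apart, differed in 474 genes, 141 higher and 333 lower in the genotoxic one (212 and 125 after quantile normalization, 166 to 385 in all with 1 rat left out).

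Each test compound was therefore set against the mean of the other 3 of its duration inside the test set, a comparison chosen after the data were seen. The actin 3' minus 5' probe difference did not overlap with that of the other compounds in ME short (2.27 ± 0.0391), Urethane short (2.73 ± 0.0513) and Urethane long (2.8 ± 0.0714, SD), nor the Gapdh difference in ME short (0.487 ± 0.0488). In DCP short the stress genes Maff (6.05 ± 0.27) and Atf3 (5.97 ± 0.49) were higher, with the stress cytokine gene Gdf15 at 5.10 ± 0.13 (adjusted p = 1.49e-15) and Myc at 4.37 ± 0.43. Onecut1 (-2.48 ± 0.76), Rgs16 (-2.33 ± 0.70), Dbp (-2.31 ± 0.69) and Exph5 (-2.0 ± 0.24) were lower. In total 1385 genes were higher and 2911 lower. Of 24 amino acid stress response genes, 17 were higher, 2 were lower and 5 did not pass (20 were higher and 2 were lower adjusted over the list alone, adjusted p = 4.58e-12, 0.0562 with an estimated correlation), with Ddit3 at 2.78 ± 0.18 and Slc7a11 at 4.07 ± 0.22. Of 29 NRF2 targets, 18 were higher, 1 was lower and 10 did not pass (19 were higher and 1 was lower adjusted over the list alone, adjusted p = 8.48e-12), with Srxn1 at 4.01 ± 0.19 and Hmox1 at 3.87 ± 0.35. Among 23 p53 targets, 11 were higher, 5 were lower and 7 did not pass (12 were higher and 6 were lower adjusted over the list alone, adjusted p = 0.002), with Mdm2 at 1.77 ± 0.086. Dbp, a member of the clock gene score, did not pass with the score as a covariate (-0.204, adjusted p = 0.455). Onecut1 did not pass without some rats; Dbp without DCP short 1; and Rgs16 without DCP short 2 (adjusted p up to 0.126).

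In DCP long the cyclin gene Ccna2 (4.03 ± 0.39) and the glutathione transferase gene Gstp1 (3.51 ± 0.26) were higher, with Fam111a (3.75 ± 1.10) and Lcn2 (3.66 ± 1.03). Obp3 was lower, at -6.96 ± 0.35 (adjusted p = 2.14e-10), with Dhrs7l1 (-5.69 ± 0.40), Cyp3a9 (-4.64 ± 0.48) and Mup5 (-4.39 ± 0.23). In total 1819 genes were higher and 2031 lower. Out of 40 proliferation genes, 36 were higher and 4 did not pass (38 were higher adjusted over the list alone, adjusted p = 8.86e-24, 0.125 with an estimated correlation), with Mki67 at 3.26 ± 0.34 and Cdk1 at 3.21 ± 0.33. Out of 20 male growth hormone genes, 14 were lower and 6 did not pass (14 were lower adjusted over the list alone, adjusted p = 1.15e-07, 0.104 with an estimated correlation), with Cyp2c11 at -2.26 ± 0.26. Of 6 cholangiocyte and oval cell markers, 4 were higher and 2 did not pass (4 were higher adjusted over the list alone, adjusted p = 0.014, 0.125 with an estimated correlation), with Anxa2 at 1.72 ± 0.16. Fam111a and Lcn2 did not pass without some rats (adjusted p up to 0.0971).

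In ME short the heme synthesis gene Alas1 (1.98 ± 0.34) and Meox2 (1.59 ± 0.27) were higher, with Bcl3 (1.44 ± 0.43) and RT1-Ba (1.41 ± 0.41). Atf3 (-2.40 ± 0.49), the hormone gene Fgf21 (-1.96 ± 0.39), Slc7a1 (-1.87 ± 0.28) and Chac1 (-1.82 ± 0.19, adjusted p = 3.05e-05) were lower. In total 485 genes were higher and 460 lower (549 to 936 with 1 rat left out). Among 24 amino acid stress response genes, 15 were lower and 9 did not pass (1 was higher and 19 were lower adjusted over the list alone, adjusted p = 4.17e-14, 0.072 with an estimated correlation), with Slc7a11 at -1.65 ± 0.22. Without DCP in the reference, 283 genes passed, and Bcl3 (1.54), RT1-Ba (1.51), Atf3 (-0.466), Fgf21 (-1.21), Slc7a1 (-0.75), Chac1 (-0.564) and Slc7a11 (-0.332) did not (adjusted p up to 0.694). With the mean of all probe sets, RT1-Ba was at 0.543 (adjusted p = 0.0688). RT1-Ba did not pass without some rats, and Bcl3 without most (adjusted p up to 0.285).

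In ME long Stac3 (2.35 ± 0.42), Obp3 (2.15 ± 0.35), Cyp3a9 (2.09 ± 0.48) and Mup5 (1.56 ± 0.23) were higher. The fragile site genes Fhit (-1.56 ± 0.14, adjusted p = 3.2e-06) and Wwox (-1.31 ± 0.11) were lower, with Ugt2b7 (-1.70 ± 0.43) and Gstp1 (-1.20 ± 0.26). In total 166 genes were higher and 141 lower (47 to 316 with 1 rat left out). Of 20 male growth hormone genes, 3 were higher and 17 did not pass (10 were higher and 1 was lower adjusted over the list alone, adjusted p = 1.03e-06, 0.0955 with an estimated correlation). The list did not pass without DCP (adjusted p = 0.698). Without DCP in the reference, 22 genes passed, and Stac3 (1.34), Obp3 (-0.192), Cyp3a9 (0.607), Mup5 (0.111), Ugt2b7 (-1.27) and Gstp1 (-0.0363) did not (adjusted p up to 0.976). Gstp1 and Cyp3a9 did not pass without some rats, and Ugt2b7 without most (adjusted p up to 0.166).

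In SN short Plcl1 (1.97 ± 0.14, adjusted p = 1.15e-07) and the G protein regulator gene Rgs4 (1.89 ± 0.38) were higher, with A2ml1 (1.83 ± 0.33) and Nim1k (1.63 ± 0.44). Noct (-2.79 ± 0.75), Gdf15 (-1.72 ± 0.13), Trim36 (-1.91 ± 0.37) and Myc (-1.63 ± 0.43) were lower. In total 1106 genes were higher and 352 lower (656 to 1530 with 1 rat left out), or 695 and 428 after quantile normalization. Out of 24 amino acid stress response genes, 1 was higher, 7 were lower and 16 did not pass (1 was higher and 8 were lower adjusted over the list alone, adjusted p = 6.16e-07, 0.34 with an estimated correlation), with Slc7a11 at -1.25 ± 0.22 and Chac1 at -0.99 ± 0.19. This list did not pass without DCP (adjusted p = 0.817). Without DCP in the reference, 147 genes passed, and Nim1k (1.4), Noct (-2.26), Gdf15 (-0.0262), Myc (-0.198), Slc7a11 (0.123) and Chac1 (0.368) did not (adjusted p up to 0.945). Nim1k, Noct and Myc did not pass without some rats (adjusted p up to 0.16).

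In SN long Obp3 (2.48 ± 0.35), Dhrs7l1 (2.11 ± 0.40), Stac3 (1.92 ± 0.42) and the ornithine aminotransferase gene Oat (1.68 ± 0.18, adjusted p = 0.000263) were higher. Cdkn1a (-1.76 ± 0.32), Gsta3 (-1.50 ± 0.25), Ugt2b7 (-2.02 ± 0.43) and the transporter gene Abcc3 (-1.32 ± 0.35) were lower. In total 331 genes were higher and 200 lower (132 to 542 with 1 rat left out). Among 29 NRF2 targets, 8 were lower and 21 did not pass (1 was higher and 13 were lower adjusted over the list alone, adjusted p = 2.55e-06, 0.123 with an estimated correlation). Without DCP in the reference, 53 genes passed, and Obp3 (0.18), Dhrs7l1 (0.239), Stac3 (0.858), Ugt2b7 (-1.63), Gsta3 (-1.2) and Abcc3 (-1.28) did not (adjusted p up to 0.913). Stac3 and Ugt2b7 did not pass without some rats; Abcc3 without most; and Dhrs7l1 without SN long 1 (adjusted p up to 0.221).

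In Urethane short Onecut1 (2.66 ± 0.76) and the mitochondrial carrier gene Slc25a25 (1.30 ± 0.29) were higher, with Fbxl17l1 (1.39 ± 0.39) and Mfsd2a (1.19 ± 0.33). Maff (-3.03 ± 0.27, adjusted p = 1.75e-06), Atf3 (-3.10 ± 0.49), the oxidative stress gene Osgin1 (-2.17 ± 0.35) and Fam111a (-3.74 ± 1.10) were lower. In total 367 genes were higher and 422 lower (195 to 885 with 1 rat left out), or 524 and 376 after quantile normalization. Out of 29 NRF2 targets, 10 were lower and 19 did not pass (11 were lower adjusted over the list alone, adjusted p = 4.77e-08, 0.151 with an estimated correlation), with Srxn1 at -1.66 ± 0.19. The list did not pass without DCP (adjusted p = 0.261). Without DCP in the reference, 380 genes passed, and Onecut1 (2.06), Fbxl17l1 (0.953), Mfsd2a (1.25), Fam111a (-3.28), Atf3 (-1.25) and Srxn1 (-0.358) did not (adjusted p up to 0.339). Fbxl17l1, Mfsd2a and Slc25a25 did not pass without some rats, and Fam111a and Onecut1 without most (adjusted p up to 0.243).

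In Urethane long Gpx2 (3.23 ± 0.57) and Mybl1 (2.15 ± 0.30) were higher, with Obp3 (2.33 ± 0.35) and Dhrs7l1 (2.24 ± 0.40). The mitosis genes Ccna2 (-3.87 ± 0.39), Cdkn3 (-3.66 ± 0.41) and Ect2 (-3.14 ± 0.33) and the heme synthesis gene of red cells, Alas2 (-3.05 ± 0.34), were lower. In total 619 genes were higher and 795 lower (668 to 1417 with 1 rat left out). Of 40 proliferation genes, 33 were lower and 7 did not pass (34 were lower adjusted over the list alone, adjusted p = 1.97e-27, 0.0649 with an estimated correlation), with Mki67 at -2.94 ± 0.34. Out of 23 p53 targets, 9 were higher and 14 did not pass (10 were higher adjusted over the list alone, adjusted p = 3.02e-07), with Mdm2 at 1.82 ± 0.086, Ccng1 at 1.63 ± 0.12 and Cdkn1a at 1.78 ± 0.32. Of 29 NRF2 targets, 15 were higher, 1 was lower and 13 did not pass (20 were higher and 1 was lower adjusted over the list alone, adjusted p = 4.09e-10), with Nqo1 at 1.18 ± 0.21. Of 6 erythroid markers, 4 were lower and 2 did not pass (5 were lower adjusted over the list alone, adjusted p = 6.9e-05, 0.0649 with an estimated correlation), with Hbb at -1.91 ± 0.24. With DCP out of the reference, Obp3 (0.0117) and Dhrs7l1 (0.383) did not pass (adjusted p up to 0.989). 

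Over the 4 test compounds, 2408 genes were higher and 1813 lower in the long than in the short groups. Lcn2 (1.95 ± 0.63), Ugt2b7 (1.49 ± 0.26), Dbp (1.38 ± 0.42) and Phgdh (1.37 ± 0.24) rose, and Egr1 (-2.70 ± 0.27), Atf3 (-2.32 ± 0.30), Maff (-2.04 ± 0.16, adjusted p = 9.41e-08) and the chemokine gene Cxcl1 (-1.97 ± 0.46) fell. Out of 14 macrophage markers, 11 fell and 3 did not pass (11 fell adjusted over the list alone, adjusted p = 0.00048, 0.631 with an estimated correlation), with Cd163 at -0.83 ± 0.14. With the clock gene score as a covariate Lcn2 (1.78) and Dbp (0.247) did not pass (adjusted p up to 0.101).

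Placement asked whether genes chosen on the other compounds of both classes (50 up and 50 down) put a compound on its own side. With levels relative to the own control, 6 of 6 left-out compounds fell on the side of their class at the short duration, which 2 of 20 ways of assigning the class labels reached (highest other 4). No share under 2 of 20 is possible, since a labeling and its mirror score alike. At the long duration 4 of 6 did, as in 6 of 20 labelings. DEN (score -0.115) and Ethionine (1.51) fell on the other side, with positive scores on the genotoxic side. Unchanged groups simulated against the same shared controls gave 6 of 6 at each duration in 100 of 100 simulations, so the short placement cannot be told from the error of the shared controls, and the long one lies below what that error alone gave. With levels as deposited, the planned form, which also carries the level difference between the sets, 6 of 6 did at the short (highest other 3) and 5 of 6 at the long duration (highest other 4), each in 2 of 20 labelings. Among the test groups, long ones scored -0.762 ± 0.111 for DCP, -1.05 ± 0.0715 for ME, -1.26 ± 0.0764 for SN and -0.6 ± 0.0498 for Urethane with levels as deposited (SD, n = 3), beside -0.897 ± 0.0315 and -1.5 ± 0.0404 for the genotoxic and nongenotoxic controls. Short ones scored 0.545 ± 0.094 for DCP, 0.0918 ± 0.181 for ME, 0.0509 ± 0.0518 for SN and -0.0655 ± 0.0168 for Urethane, beside 0.178 ± 0.29 and -0.433 ± 0.171. Relative to the mean of both controls, long groups scored from -1.3 (SN) to -0.618 (Urethane), where each control relative to itself scored -1.34, and short ones from 0.276 (ME) to 0.39 (DCP), where the controls scored -0.0717. Centred on the mean of the test set, which fixes the balance of the signs, scores lay between -0.288 (SN) and 0.398 (Urethane) at the long and between -0.0368 and 0.0769 at the short duration.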

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

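The comparisons of compounds with each other and of the long with the short group of 1 compound, and both tests of the PPAR alpha pattern, were chosen after results were seen. Class by duration passed in 4431 genes with rats, not compounds, as replicates. The 5 list results chosen here use no controls. PPAR alpha targets were lower in Clofibrate long than in Clofibrate short (adjusted p = 4.17e-24), with 18 of 44 members lower and none higher (31 lower adjusted over the list alone). Proliferation genes were higher in DEN than in AAF long (adjusted p = 8.64e-27, 0.0863 with an estimated correlation, 36 of 40 members higher, none lower). NRF2 targets were lower there (adjusted p = 4.22e-08, 0.213 with an estimated correlation, 20 of 29 lower, 2 higher). The p53 targets were higher in DEN than in AAF short (adjusted p = 2.52e-07, 10 of 23 higher, none lower), and higher in Ethionine than in Clofibrate long (adjusted p = 0.000143, 15 higher, 4 lower). Probe sets without exactly 1 gene symbol, which no comparison above uses, also differed between the classes, 107 of 4434 at the short (58 higher, 49 lower) and 261 at the long duration (121 and 140).

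PPAR alpha targets rose in Clofibrate short (median 0.503 ± 0.115, SE over 44 members) and not in Clofibrate long (median -0.0753 ± 0.0565). High targets in the controls cannot explain the long minus short difference, which uses none (median -0.576 ± 0.11, bound -0.252). They could still hide a rise in Clofibrate long. An exchange of labels with Dioxane long is argued against by that group's median (-0.118 ± 0.0679, where 0.252 or more was needed), while an exchange with Ethionine long cannot be told apart from a real difference, since its median of 0.188 ± 0.277 spans the bound. The hour of necropsy may account for part, since the clock gene score was -1.61 in Clofibrate short and 1.73 in Clofibrate long and Cd36 rose in Dioxane and Ethionine short too (1.48 each), but the list passed in Clofibrate short with the score as a covariate (adjusted p = 7.05e-17 with the preset correlation, but without the score 0.2 with an estimated correlation) and was lower in Dioxane than in Clofibrate short (adjusted p = 1.38e-12, 0.517 with an estimated correlation). The compound and its dosing remain open as a biological explanation and were not tested.

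Other splits of the same arrays were counted for each comparison of at least 3 arrays or compounds per side. With 10 splits, too few for a share under 0.05, the real and the highest other count were 590 and 1224 in class short (4 of 10 gave at least 590), 1294 and 6169 in class long (10 of 10 gave at least 1294), 935 and 1 in AAF short, 3538 and 1324 in AAF long, 101 and 3 in MeDAB short, 5898 and 0 in MeDAB long, 1838 and 0 in DEN long, 605 and 1 in Dioxane short, 18 and 1 in Dioxane long, 319 and 18 in Clofibrate short, 15 and 2 in Clofibrate long, 567 and 214 in Ethionine short, 5842 and 1 in Ethionine long, and 474 and 0 between the controls. They were 197 and 281 for AAF against MeDAB short, 5405 and 1294 for the long pair, 3419 and 1507 for DEN against AAF long, 5422 and 11 for DEN against MeDAB long, 0 and 1 for Dioxane against Clofibrate at each duration, and 6113 and 0 for Ethionine against Clofibrate long. Class counts and regroupings do not compare evenly, since mixed groups cancel part of the controls' error that the classes carry in full.

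Chance was excluded, at 1 of 100 splits, for the genotoxic duration (6332, highest other 5585), the nongenotoxic duration (3962, 3407), class by duration (4431, 1304) and duration test (4221, 1418). Chance was also excluded inside the test set for DCP short (4296, 148) and DCP long (3850, 3494). ME short (945, 243) and Urethane long (1414, 419) had 1 of 100 too. ME long (307, 3573), SN short (1458, 4040), SN long (531, 3375) and Urethane short (789, 4092) had 2 of 100. Their highest counts point to a structure of the samples. Other splits scatter the DCP rats, so chance is not excluded for ME, SN and Urethane. Against both controls 1 of 84 splits gave as many in each comparison (8097 to 8736, highest other 6478 to 7111). The compound and the apparent separate normalization cannot be told apart there.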

How the results depend on the processing

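The clock gene score, leaving out replicate 1 of both controls and leaving DCP out of the reference were chosen after the data were seen, as were all comparisons inside the test set and all pairs of compounds. Of 326 gene results, 184 kept their direction and their call under every alternative that gave a value, and 261 under every left-out rat. Of 66 list results, 56 did so under every alternative other than the estimated correlation, and 63 under every left-out rat. With an estimated correlation 20 of the 66 list calls stood. Gene calls that ended numbered 7 of 326 with no filter, 1 of 308 with a stricter filter, 4 of 324 with the mean of all probe sets of a gene, 4 of 326 with trend and robust, 1 of 326 with quantile normalization and 6 of 326 with all 65 arrays fitted together. They numbered 47 of 326 with only the arrays of the compared groups, 2 of 141 with all 6 controls and 2 of 54 with no controls, and 54 and 32 of 54 with compound as a random block and as replicates. With the clock gene score 39 of 326 ended and 3 more changed sign, without replicate 1 of both controls 16 of 203 ended, and without DCP 30 of 58 ended and 3 more changed sign. Beside the list calls named with their results, those that ended were pancreas markers in MeDAB long with no filter or quantile normalization (adjusted p up to 0.278), leukocyte markers in AAF long and PPAR alpha targets in Clofibrate long with the stricter filter, all 65 arrays and all 6 controls (up to 0.272), the latter also with the mean of all probe sets (0.107), endothelial markers in Ethionine long with all 6 controls (0.074), and clock genes in the nongenotoxic duration with the stricter filter (0.0544). MeDAB long, Ethionine long, genotoxic duration, DCP inside its set and duration test stayed within 1.5 times their counts under all alternatives and left-out rats, as did the held-out placements. The stricter filter left 308 gene and 65 list results.

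With no filter the count was 850 in controls. The stricter filter, which tests fewer genes, gave 163 in controls and 5572 in DCP short, 5304 in DCP long, 5243 in ME short, 5250 in ME long, 5130 in SN short, 5202 in SN long, 5422 in Urethane short and 5285 in Urethane long against both controls. The mean of all probe sets gave 59 in MeDAB short and 25 in shared genotoxic short. Quantile normalization gave 24 in Clofibrate long, 3 in Dioxane against Clofibrate short and 5442 in ME short, 5397 in SN short and 5419 in Urethane short against both controls. All 65 arrays in 1 fit gave 33 in Dioxane long, 30 in Clofibrate long, 336 in AAF against MeDAB short, 27 in Dioxane against Clofibrate short, 142 in shared nongenotoxic short and 143 in ME long inside the test set. With only the arrays of the compared groups, and so fewer to estimate the spread, counts were 410 in AAF short, 1214 in AAF long, 5 in MeDAB short, 291 in Dioxane short, 37 in Dioxane long, 135 in Clofibrate short, 28 in Clofibrate long, 13 in Ethionine short, 0 in AAF against MeDAB short, 2925 in AAF against MeDAB long, 1266 in DEN against AAF long, 1 in Dioxane against Clofibrate long, 2 in shared genotoxic short, 6 in shared nongenotoxic short and 430 in ME short, 202 in ME long, 877 in SN short, 337 in SN long and 363 in Urethane short inside the test set. With those arrays only, Rprm and Efemp1 in class short; Noct, Zfp354a, Mid1ip1 and Rtp3 in AAF short; Gpx2 and Ptprc in AAF long; Usp2, Egr1, Onecut1 and Socs2 in Dioxane short; Gsta3 and Cers6 in Dioxane long; Enc1, Sult2a6, Socs2 and Rprm in Clofibrate short; Syne4 and Cers6 in Clofibrate long; Ugt2b in controls; and, inside the test set, Bcl3 and RT1-Ba in ME short; Cyp3a9, Ugt2b7 and Gstp1 in ME long; Noct in SN short; Stac3, Ugt2b7 and Abcc3 in SN long; Onecut1, Fbxl17l1, Slc25a25, Mfsd2a and Fam111a in Urethane short did not pass (adjusted p up to 0.152). Against all 6 controls, which mixes 2 sets that appear to have been normalized apart, counts were 1478 in AAF short, 532 in MeDAB short, 3350 in DEN long, 1530 in Dioxane short, 359 in Dioxane long, 811 in Clofibrate short, 232 in Clofibrate long, 1400 in Ethionine short, 168 in shared genotoxic short, 289 in shared nongenotoxic short, 1320 in shared genotoxic long and 66 in shared nongenotoxic long. Other calls that ended under no filter, the mean of all probe sets, trend and robust, all 65 arrays, all 6 controls or a replicate block were those of Psat1 and Efemp1 in class short, Fam111a in DEN short, Ifgga2l1 and Slc25a30 in MeDAB short, Rprm in Clofibrate short, Cers6, Hacl1 and Rif1 in Clofibrate long, Bcl3 and RT1-Ba in ME short, Cyp3a9 in ME long, Fam111a, Onecut1 and Fbxl17l1 in Urethane short and Acsm3 between the controls (adjusted p up to 0.419). With no controls, which leaves the level difference between the sets in, counts were 4788 in class short and 6326 in class long, with compound as a random block 5 and 0, and with compound means 2 in class long.

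With the clock gene score as a covariate counts were 182 in class short, 154 in Dioxane short, 56 in Dioxane long, 43 in Clofibrate short, 35 in Clofibrate long, 20 in Ethionine short, 1113 in nongenotoxic duration, 2140 in class by duration, 110 in AAF against MeDAB short, 5 in shared nongenotoxic short, 14 in shared nongenotoxic long and 426 in ME short and 183 in ME long inside the test set. Dbp (0.729) and Usp2 (0.144) in the nongenotoxic duration and Dbp (-0.0905) in class by duration changed sign, and Dbp passed in the nongenotoxic duration with the other sign (adjusted p = 0.0255). Dbp, Bmal1 and Npas2 are members of the score. With the score, Fam111a (-4.64) in DEN short; Rcan2 (0.973) and Ppp1r10 (-0.838) in Clofibrate long; and, inside the test set, Bcl3 (0.766) and Fgf21 (-1.29) in ME short; Cyp3a9 (1.94) in ME long; Ugt2b7 (-1.52) and Abcc3 (-1.38) in SN long did not pass (adjusted p up to 0.326). Without replicate 1 of both controls counts were 165 in class short, 753 in class long, 534 in AAF short, 78 in Dioxane long, 55 in Clofibrate long, 171 in controls, 24 in shared genotoxic short, 169 in shared nongenotoxic short and 23 in shared nongenotoxic long. There, Stac3, Trim36, Psat1, Upk1b, Efemp1 and Phlda3 in class short; Snx10, Got1 and Srxn1 in class long; Cdkn1a, Slc25a32, Chac1 and Slc25a30 in MeDAB short; Fam111a in DEN short; Rcan2 in Clofibrate long; and Acsm3 in controls did not pass (adjusted p up to 0.147). Without DCP in the reference counts were 283 in ME short, 22 in ME long, 147 in SN short, 53 in SN long and 380 in Urethane short inside the test set. Obp3 (-0.192) in ME long, and Slc7a11 (0.123) and Chac1 (0.368) in SN short, changed sign there. DCP differed from the other 3 in 4296 and 3850 genes, so a mean that holds DCP carries its changes with the opposite sign.

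With single rats left out, counts ran from 205 to 720 in class short, 778 to 1812 in class long, 399 to 1356 in AAF short, 12 to 175 in MeDAB short, 857 to 1513 in DEN short, 203 to 586 in Dioxane short, 3 to 70 in Dioxane long and 46 to 393 in Clofibrate short. They ran from 2 to 44 in Clofibrate long, 70 to 1179 in Ethionine short and 166 to 385 in controls. Inside the test set, ME short had 549 to 936, ME long 47 to 316 and SN short 656 to 1530. There, SN long had 132 to 542 and Urethane short 195 to 885. The others ran from 668 to 1417 in Urethane long inside its set, 21 to 497 in AAF against MeDAB short, 0 to 51 in Dioxane against Clofibrate short, 5 to 49 in shared genotoxic short, 21 to 157 in shared nongenotoxic short, 420 to 730 in shared genotoxic long and 2 to 19 in shared nongenotoxic long. Where a left-out rat leaves 1 in its group, that rat is taken to vary like the others.

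With the replicate number as a block, class short had 581 and class long 1284 called genes, no count moved by over 1.5 times, 7 of 326 gene calls ended and no list call did. The numbers do not pair the rats: rats with the same number deviated together, with every correlation over 0.1, in only 1 of 16 comparisons, ME long with ME short (all correlations lay between -0.197 and 0.175). Genes under log2 6.03 in all but 1 array of a fit (5.65 inside the test set) were not tested.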

Other observations

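The tests of a variant between rats and of the compounds for Ugt2b were chosen after results were seen, as was a second condition in the clock covariate test named there. Ugt2b lay below 10 in 11 of 65 rats, with no rat between 9.58 and 12.7 and a range of 5.47 to 13.6. A variant in its chromosomal neighbourhood stays open, since of the 20 genes that deviated most closely with it inside groups 1 lay on its chromosome (0.654 drawn at random), a count that was to argue against it, but that gene, Ugt2b1, of the same family, was the closest of all, which was weighed after it was seen. A variant of the gene itself that differs between rats has the values it needs, since 7 of 15 groups outside the nongenotoxic set held rats over 3 log2 apart. If the low rats were placed at random, some group would hold 3 in 0.0783 of 100000 draws. That fixes neither this control nor its high treated rats, so it cannot decide between chance placement and the compounds.

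The genes shared by the 3 short nongenotoxic groups may reflect the hour of necropsy, which the labels do not give for the controls. Clock gene scores were -1.61, -1.62 and -2.04 in Clofibrate, Dioxane and Ethionine short, and 0.333 ± 1.31 (SD, n = 3) in their control, where rat 1 (-1.18) stood apart from rats 2 and 3 (1.15 and 1.03), and without it the shared count was 157. Of 85 shared genes outside the score, 56 (65.9%) moved as their slope on the score inside the test set gives, against 55.8% of 9950 other genes (exact binomial test against that share, two-sided p = 0.064), between the 70% set for this explanation and the 55% set against it. With the score as a covariate the shared count went from 88 to 5, which the bound written beforehand counts in favour, but after that count was seen the median absolute difference was required to fall as far, and it went from 0.942 to 0.755 with a median SE of 0.198 and 0.213 and all directions kept. The calls ended as differences shrank and errors grew, so hour and compounds cannot be told apart.

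AAF long 1 had a larger difference between its 3' and 5' actin probes (3.8626) than AAF long 2 and 3 (2.7024 and 2.7568), though DEN long 2 was close (3.8002), and 4188 genes were called in AAF long without it. Mx2 and Raph1 were called in some probe sets only. Fam111a varied over 3 log2 in 13 of the 22 groups.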
